A study of Mus musculus with 12 samples.

How the data were processed

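Sorted hematopoietic stem cells of 12 mice were profiled by RNA sequencing of total RNA, with 1 library per mouse and 3 mice for each of 4 genotypes. The deposited table held raw counts per gene for all 12 libraries, with 27179 genes listed by NCBI Gene number. The values were whole numbers, and no normalization by the authors was found in them. Alignment with STAR 2.5.3 to mm10 is credited to the submitters' processing notes. The read counter, the gene annotation, the strandedness and any filter are not given in the sources used here. Symbols and positions came from the RefSeq annotation of the same assembly, which matched 25275 of the gene numbers. The other 1904 were kept in the tests by number, and held 0.546 to 2.45% of the counts of a library.

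Libraries held 24529611 to 34065910 counts. Each group was compared in a fit of all 12 libraries with edgeR 4.0.16 (R 4.3.3): TMM factors, the filterByExpr filter by group, group means without an intercept, and quasi-likelihood F tests, which are two-sided. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the 14473 genes tested, and the biological coefficient of variation was 0.139. The contrasts were E against WT, CE against C, C against WT, CE against E, and the difference between the first 2. CPM are counts scaled to the library's effective size. Intervals for single counts were not used, since replicates carry the error.

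The pipeline was tested on simulated data of the same size, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. It recovered 40.3 to 44.8%, 65.7 to 77.6% and 92.4 to 97.0% of them in the 2-group comparisons, and 10.4%, 64.2% and 84.8% in the test of the difference. Of its calls, 2.29 to 5.75% were false. Members of the nuclear oxidative phosphorylation list were raised as well, and calls of them counted as true. The simulated counts were independent between genes, with no sex difference and no length or GC trends. These rates therefore need not hold for the real libraries.

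Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided, adjusted over the 29 lists of a comparison, each with at least 4 tested members. The lists cover stem and progenitor cell programs, cell cycle, growth and metabolism, interferon and inflammation, cell death and stress, other blood and stromal cell types, genes near Casp1 and sex-specific transcripts. Beside them stand camera with an estimated correlation and fry. The lists, comparisons, tests and the alternatives up to the removal of single libraries were chosen before the data were examined. Mitochondrial ribosomal RNA genes belong to no list.

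The genes named in the text follow a rule fixed in advance. It takes Myc, Casp1 and Casp4 in every comparison. It takes the 8 genes with the largest log2 fold change in each direction among those that passed, with an average log2 CPM of at least 1, a symbol that is not a predicted or clone name, and groups that do not overlap. It takes up to 3 members past the threshold of each of the 6 lists with the smallest camera p, or the 2 with the smallest p as values. Where fewer than 5 genes passed, it takes the 5 with the smallest unadjusted p as values. Genes named outside the rule are marked where they appear, and some results under it are not reported here.

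Alternatives replaced TMM with the RLE factors, the low-count filter with none (at least 1 count) or a stricter one (1 CPM in 6 libraries), and edgeR with DESeq2 1.42.0 or limma voom with quality weights. Others fitted only the groups compared, added the replicate number as a block or a covariate for Y-linked transcripts (over 1 CPM in sum), asked for 2-fold changes, or left out each library in turn. After the data were seen, further alternatives removed trends of log2 CPM on transcript length and GC content per library (longest transcript of GENCODE, 13982 of 14473 tested genes with a value), left out C1 and C3 together, left out genes on chromosomes X and Y, or gave named genes the Y-linked covariate. Leaving out C1 and C3 together leaves 1 library in group C, which is assumed to vary like the other groups. All 12 libraries were used. The labels give no batch and do not pair the mice.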

Results

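Total RNA of sorted hematopoietic stem cells, the cells that sustain all blood lineages, was sequenced in 12 libraries from C57BL/6J mice of 4 genotypes, with 3 mice per genotype. The genotypes crossed the Eµ-myc transgene, which places Myc under an immunoglobulin heavy chain enhancer, with the joint loss of Casp1 and Casp11, which encode the inflammatory caspases of the pyroptosis pathway. Casp11 is listed as Casp4 in the gene annotation. The libraries keep the names of their labels. WT2, WT3 and WT4 came from wild-type mice (group WT) and E1, E2 and E3 from Eµ-myc mice (group E). C1, C2 and C3 came from the caspase double knockout (group C), and CE1, CE2 and CE3 from Eµ-myc mice on the double knockout background (group CE). Total counts were 28945903, 28999352 and 24724773 in WT2, WT3 and WT4. They were 24529611, 30055597 and 24672389 in E1, E2 and E3. They were 28353953, 34065910 and 30661280 in C1, C2 and C3, and 28723285, 28271055 and 31100277 in CE1, CE2 and CE3. A count was present for 22900 genes in C1 and 21247 in C3, against 17310 to 18863 in each of the other libraries. The first principal component of the log2 CPM (counts scaled to the effective library size) carried 28.3% of the variance. It separated all libraries with the caspase knockout label from all libraries without it, and WT4 had the most extreme score on the second component.

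The targeted genes came first. Casp1 (gene 12362, chromosome 9, 5298517 to 5307281, mm10), which encodes the caspase that matures interleukin-1 family cytokines, was at 39.1 ± 9.0 CPM in WT and 42.1 ± 3.82 in E (SD, n = 3 each). It was at 5.90 ± 0.70 CPM in C and 6.12 ± 0.56 in CE (SD, n = 3 each). It fell 6.64-fold in C against WT (log2 -2.73, SE 0.17, adjusted p = 9.15e-07) and 6.87-fold in CE against E (log2 -2.78, SE 0.17, adjusted p = 7.25e-07). Casp4 (gene 12363, chromosome 9, 5308849 to 5336791) was at 13.01 ± 1.31 CPM in WT, 14.7 ± 2.40 in E, 8.98 ± 1.66 in C and 10.8 ± 2.51 in CE (SD, n = 3 each). Its differences did not pass the test in C against WT (log2 -0.54, SE 0.19, adjusted p = 0.11) or in CE against E (log2 -0.44, SE 0.19, adjusted p = 0.177). In C against WT it passed with no filter on low counts (adjusted p = 0.0237) and with limma voom (adjusted p = 0.0371). Its gene-level counts therefore did not settle the Casp11 part of the label. Myc (gene 17869, chromosome 15, 61985341 to 61990361) was at 425.9 ± 28.5 CPM in WT, 433.6 ± 13 in E, 326.7 ± 8.86 in C and 366.9 ± 36.9 in CE (SD, n = 3 each). Neither E against WT (log2 0.03, SE 0.10, adjusted p = 0.967) nor CE against C (log2 0.17, SE 0.10, adjusted p = 0.999) passed for Myc. Its counts therefore did not check the transgene label. For the caspase label, Myc did not pass in C against WT (log2 -0.38, SE 0.10, adjusted p = 0.0579) or in CE against E (log2 -0.24, SE 0.10, adjusted p = 0.156). In C against WT Myc passed with no filter on low counts (adjusted p = 0.0206), DESeq2 (0.00319), limma voom (0.00685) and the replicate block (0.0223), and without WT4 (0.0112). In CE against E Myc passed with limma voom (adjusted p = 0.0248). Y-linked transcripts were present in C1, C2, C3, CE1 and CE2 and near 0 in the other libraries, including CE3, so the caspase label and the sex of the mice nearly coincided.

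**Figure D1:**
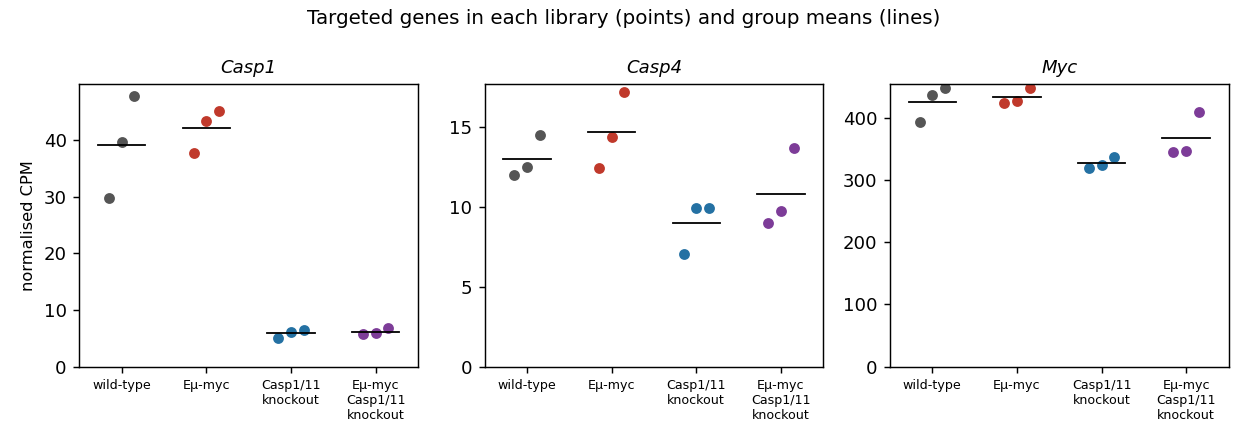
CPM of Myc, Casp1 and Casp4 in each of the 12 libraries by group, with the mean of 3 libraries and a linear axis from 0. Casp1 lay between 5.10 and 6.76 CPM in the libraries with the caspase knockout label and between 29.8 and 47.8 CPM in the others, while the Casp4 and Myc differences did not pass the edgeR test.

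The effect of the transgene with intact caspases was asked by E against WT. Selp, which encodes the adhesion molecule P-selectin (chromosome 1, 164115264 to 164150026), rose 2.28-fold, from 14.4 ± 0.99 CPM in WT to 32.9 ± 4.33 in E (SD, n = 3 each, log2 1.19, SE 0.14, adjusted p = 0.00253). The other 6 genes that rose lay on chromosome 19 among the 17 tested genes between 28963920 and 30093726 (mm10): Plpp6, Cdc37l1, Ak3, Ric1, Ermp1 and Uhrf2. Their rises ranged from 1.57-fold for Plpp6 (adjusted p = 0.0484) to 1.73-fold for Cdc37l1 (adjusted p = 0.045). Ak3, a mitochondrial adenylate kinase gene, was at 66.5 ± 5.68 CPM in WT and 109.4 ± 2.53 in E (SD, n = 3 each). Genes of the surrogate light chain, which pairs with the heavy chain in early B cells, fell. Igll1 fell 5.12-fold (log2 -2.36, SE 0.35, adjusted p = 0.0168) and Vpreb1 4.94-fold (log2 -2.30, SE 0.34, adjusted p = 0.0161). Vpreb2 fell 7.95-fold from a mean of 2.44 CPM (adjusted p = 0.0447). Vpreb1 and Vpreb2 are near-identical copies, and reads may have been assigned to either. Bfsp2, a filament protein gene, fell 2.89-fold (adjusted p = 0.00456). Gm15915, a predicted gene named after its values were seen, fell as well (adjusted p = 0.016).

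In total 12 of 14473 genes passed in E against WT, 7 higher and 5 lower. In all 12 every library of one group lay above every library of the other. Of all genes tested, 8.02% were separated in this way, where chance gives 10%. Of the 29 fixed gene lists, 14 passed the camera test with a preset correlation, 2 higher and 12 lower, and none passed with an estimated correlation. The hematopoietic stem cell (HSC) identity list passed as higher (25 of 30 members higher, median log2 0.21, camera adjusted p = 1.34e-07, adjusted p = 0.182 with an estimated correlation). None of its members passed over all genes, and 1 passed adjusted over the list alone. The stem cell transcription factors Hlf (log2 0.59, SE 0.12, adjusted p = 0.112) and Mecom (log2 0.52, SE 0.16, adjusted p = 0.463) stood at the top of it. The B lineage list passed as lower (median log2 -0.32, camera adjusted p = 0.00055, adjusted p = 0.531 with an estimated correlation). Of its 25 members 3 were lower over all genes and none higher, and 10 lower and 1 higher adjusted over the list alone. The erythroid lineage list passed as lower (median log2 -0.51, camera adjusted p = 0.000362, 0.584 with an estimated correlation). So did the basophil, eosinophil and mast lineage list (median log2 -0.52, camera adjusted p = 0.00055, 0.475 with an estimated correlation), and no member of either passed over all genes. Without WT3 the B lineage list did not pass (camera adjusted p = 0.242), and without E3 or WT2 the erythroid list did not (0.312 and 0.339).

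Growth and metabolic lists lay lower in E than in WT by small amounts, and no member of them passed over all genes or adjusted over the list alone. Cytosolic ribosomal proteins had 72 of 73 members lower (median log2 -0.19, camera adjusted p = 8.54e-10, adjusted p = 0.604 with an estimated correlation). Rps29 was at log2 -0.34 (SE 0.17, adjusted p = 0.768) and Rpl27 at log2 -0.30 (SE 0.15, adjusted p = 0.768). Nuclear-encoded oxidative phosphorylation genes had 47 of 50 members lower (median log2 -0.20, camera adjusted p = 1.19e-08, adjusted p = 0.531 with an estimated correlation). Ndufv1 was at log2 -0.28 (adjusted p = 0.72) and Cyc1 at log2 -0.27 (adjusted p = 0.747). Ribosome biogenesis and nucleolar MYC targets had 50 of 55 members lower (median log2 -0.16, camera adjusted p = 4.93e-08, adjusted p = 0.531 with an estimated correlation). Odc1, a polyamine enzyme gene, was at log2 -0.39 (adjusted p = 0.533) and Wdr74 at log2 -0.33 (adjusted p = 0.629). Aminoacyl-tRNA synthetases passed in the same direction (median log2 -0.11, camera adjusted p = 0.00451, 0.531 with an estimated correlation). Glycolysis genes did too (median log2 -0.13, camera adjusted p = 0.0464, 0.701 with an estimated correlation). The synthetase list did not pass without E3 or WT2 (camera adjusted p = 0.34 and 0.138), nor glycolysis without E2, E3 or WT4 (0.0976, 0.158 and 0.667, the last with its direction turned).

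Of the stress and inflammatory lists, 4 passed as lower in E, and the inflammasome and pyroptosis (median log2 0.01) and interferon-gamma and antigen presentation lists (median log2 0.02) did not pass. Immediate early and heat shock genes had 27 of 29 members lower (median log2 -0.40, camera adjusted p = 1.76e-05, adjusted p = 0.531 with an estimated correlation). None passed over all genes, and 7 lower and 1 higher passed adjusted over the list alone. Atf3, a stress-induced transcription factor (log2 -3.11, SE 0.72, adjusted p = 0.248), was at 126.6 CPM in WT4 against 19.8 in WT2 and 13.5 in WT3. The list's mean log2 CPM, set to 0 at the WT mean, was 0.672 in WT4, -0.332 in WT2 and -0.34 in WT3. It was -0.169, -0.509 and -0.488 in E1, E2 and E3. Without WT4 this list and the NF-kB and TNF response did not pass (camera adjusted p = 0.456 each), nor did the chromosome 9 genes (0.383). Nr4a1 was at log2 -1.48 (SE 0.34, adjusted p = 0.248). The unfolded protein and integrated stress response list (median log2 -0.22, adjusted p = 2.44e-05, 0.531 with an estimated correlation) included Dnajb9 at log2 -0.38 (adjusted p = 0.523). Interferon-stimulated genes passed as lower with no member past the threshold over all genes or over the list alone (31 of 42 members lower, median log2 -0.13, camera adjusted p = 0.000119, 0.531 with an estimated correlation). Their call ended without WT3 (camera adjusted p = 0.0645). The NF-kB and TNF response passed as lower (median log2 -0.24, camera adjusted p = 0.000761, 0.531 with an estimated correlation). Chromosome 9 genes near Casp1 passed as higher, with no member past the threshold (15 of 18 members higher, median log2 0.19, camera adjusted p = 0.00121, 0.531 with an estimated correlation). Leaving out E1, E2, E3, WT2, WT3 or WT4 gave 7, 7, 5, 8, 6 and 21 genes, of which 7, 6, 3, 6, 4 and 9 were among the 12. Selp, Ak3 and Bfsp2 passed each time, and 1 gene passed with only the E and WT libraries in the fit. The chromosome 9 call ended with no filter on low counts and the glycolysis call with a covariate for Y-linked transcripts. Of the lists, the ribosomal protein, glycolysis and chromosome 9 calls ended once length and GC trends were removed, and 5 of the 10 splits of these libraries into groups of 3, the real one included, gave as many lists.

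The effect of the transgene without the caspases was asked by CE against C, which shares no library with the comparison above. Selp rose 2.67-fold, from 12.4 ± 1.46 CPM in C to 33.0 ± 4.60 in CE (SD, n = 3 each, log2 1.42, SE 0.14, adjusted p = 0.000509). On chromosome 19, 7 genes of the same segment rose. Cd274, an immune checkpoint ligand gene, rose 1.85-fold (log2 0.89, SE 0.14, adjusted p = 0.0141). The cytokine receptor kinase gene Jak2 rose 1.58-fold (log2 0.66, SE 0.12, adjusted p = 0.0383) and Plgrkt 1.64-fold (adjusted p = 0.0141). The other members that rose were Plpp6, Ak3, Ermp1 and Uhrf2. Vldlr, a lipoprotein receptor gene outside that segment on chromosome 19 (27216480 to 27254231), rose 1.67-fold (adjusted p = 0.038). B-cell genes fell. The B-cell transcription factor gene Pax5 fell 6.26-fold and the coactivator gene Pou2af1 6.37-fold. The antigen receptor gene Cd79a fell 5.99-fold, and Vpreb3 and Igll1 fell 5.63-fold and 5.37-fold (adjusted p = 0.00708 to 0.0246 for these 5). Cd79a was at 28.0 ± 5.64 CPM in C and 4.67 ± 0.52 in CE (SD, n = 3 each, log2 -2.58, SE 0.35). The growth factor receptor gene Gfra2 fell 7.32-fold (adjusted p = 0.00708) and the chromatin gene Cecr2 5.91-fold (adjusted p = 0.0335).

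**Figure D2:**
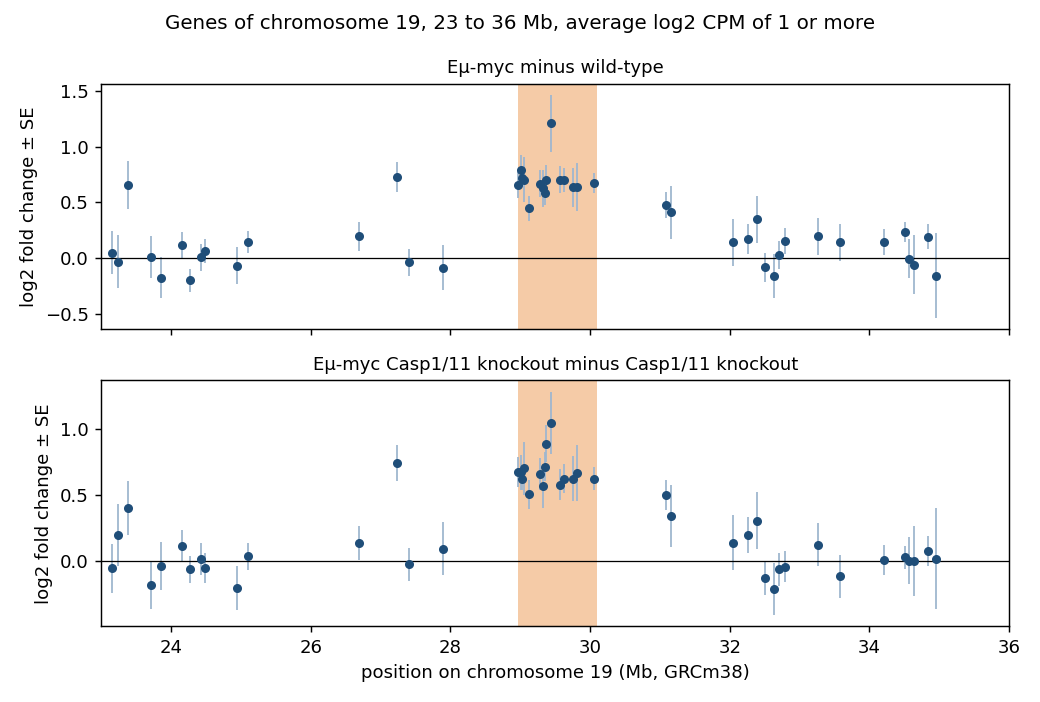
Log2 fold change of tested genes with an average log2 CPM of at least 1 against position on chromosome 19 (mm10, Mb, from 23 to 36) for E against WT and CE against C, with the segment from 28963920 to 30093726 shaded. All 17 tested genes of the segment were higher in both comparisons, with medians of 0.67 and 0.66.

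In total 30 genes passed in CE against C, 9 higher and 21 lower. In all 30 the groups did not overlap (14.9% of all genes did not overlap, where chance gives 10%). CE3 alone of these 6 libraries lacked Y-linked transcripts. With a covariate for them 9 genes passed, 6 higher and 3 lower, all among the 30. Of the lower genes named, Cd79a (log2 -2.57, SE 0.42, adjusted p = 0.0448) and Gfra2 (adjusted p = 0.0444) still passed, and so did Selp. Pax5 was then at log2 -2.44 (SE 0.47, adjusted p = 0.0934) and Pou2af1 at log2 -2.67 (SE 0.54, adjusted p = 0.127). Over the 21 genes that no longer passed, the median change was 2.22 before and 2.2 after, and the median SE 0.342 and 0.393. The B lineage list passed as lower (24 of 25 members lower, median log2 -1.42, camera adjusted p = 6.85e-24, adjusted p = 0.0591 with an estimated correlation). Of its members 10 were lower over all genes and 13 adjusted over the list alone. The HSC identity list passed as higher (29 of 30 members higher, median log2 0.23, camera adjusted p = 5.83e-13, adjusted p = 0.0331 with an estimated correlation). It was the only list call of the 5 contrasts that held with an estimated correlation. None of its members passed over all genes and 6 passed adjusted over the list alone. Mycn was at log2 0.43 (SE 0.10, adjusted p = 0.209) and Ifitm1 at log2 0.63 (SE 0.16, adjusted p = 0.255). The erythroid lineage list passed as lower (20 of 20 members lower, median log2 -1.03, camera adjusted p = 8.76e-12, adjusted p = 0.389 with an estimated correlation), and none of its members passed over all genes or over the list alone. The carbonic anhydrase gene Car1 was at log2 -1.40 (SE 0.40, adjusted p = 0.423) and Tspo2 at log2 -1.15 (SE 0.35, adjusted p = 0.521). Genes of the G2/M phase (median log2 -0.12, adjusted p = 1.01e-06, 0.74 with an estimated correlation) included Ccnb1 at log2 -0.36 (adjusted p = 0.583) and Aurka at log2 -0.23 (adjusted p = 0.882). Ribosome biogenesis and nucleolar MYC targets (median log2 -0.10, adjusted p = 0.000109, 0.74 with an estimated correlation) included Ranbp1 at log2 -0.27 (adjusted p = 0.777) and Odc1 at log2 -0.27 (adjusted p = 0.935).

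The basophil, eosinophil and mast lineage list passed as lower too, with no member past the threshold (median log2 -0.38, adjusted p = 0.00176, 0.379 with an estimated correlation). The eosinophil peroxidase gene Epx was at log2 -1.10 (adjusted p = 0.777) and the mast cell protease gene Cpa3 at log2 -0.52 (adjusted p = 0.832). S phase (median log2 -0.08, camera adjusted p = 0.0039), aminoacyl-tRNA synthetase (-0.10, 0.0229) and nuclear oxidative phosphorylation lists (-0.06, 0.0122) passed as lower. The unfolded protein and integrated stress response (-0.13, 0.00201) and the T and NK lineage (-0.35, 0.0104) passed as lower too. Interferon-gamma and antigen presentation genes passed as higher (0.07, 0.0138). With an estimated correlation these 6 lists had adjusted p = 0.389 to 0.907. Of the 34 members of the interferon-gamma list 25 were higher, and 1 passed over all genes. That member was among Selp, Vldlr and the 7 genes of the chromosome 19 segment, the genes that passed as higher in CE against C. Without CE3 the G2/M, S phase and interferon-gamma lists did not pass (camera adjusted p = 0.165, 0.501 and 0.0708), and without C2 the MYC target list did not (0.151). Without C2 or CE2 the oxidative phosphorylation (0.972 and 0.852), stress response (0.0686 and 0.164), T and NK (0.0526 and 0.286) and synthetase lists (0.471 and 0.188) did not pass. With no filter on low counts 4 of the 12 list calls were kept, and 4 lists passed as higher and 2 as lower. The G2/M, S phase, T and NK, synthetase, basophil, oxidative phosphorylation, MYC target and stress response calls ended. The Y-linked covariate ended the G2/M, S phase and interferon-gamma calls. S phase was also lost without C2 (0.287), the synthetases without C3 or CE1 (0.0629 and 0.121) and interferon-gamma without C3 (0.108). Leaving out C1, C2, C3, CE1, CE2 or CE3 gave 13, 9, 8, 2, 8 and 5 genes, of which 13, 7, 8, 2, 8 and 5 were among the 30. Selp passed each time, and none of the B-cell genes named passed in all 6. Without C1 and C3 together, a choice made after the data were seen, no gene passed with edgeR (282 at an unadjusted p under 0.05), and 4 of the 10 splits of these libraries, the real one included, gave as many lists.

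**Figure D3:**
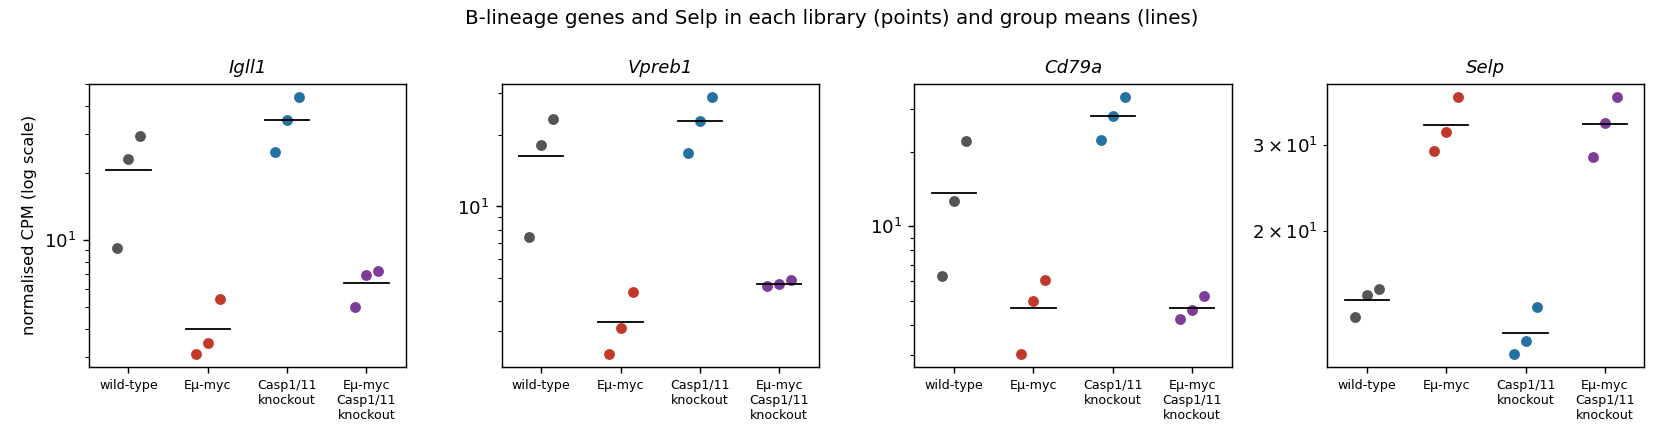
CPM of B-lineage genes and Selp in each of the 12 libraries by group, on a log axis, with group means over 3 libraries. Cd79a was at 28.0 CPM in C and 4.67 in CE, and at 13.7 in WT and 4.69 in E.

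The 2 transgene effects were compared across genes and tested for a difference gene by gene. Across 14473 genes, which are not independent replicates, the log2 fold changes of E against WT and CE against C had Pearson's r = 0.274 and Spearman's rho = 0.236. With no filter on low counts r was -0.00371, and with the stricter filter 0.435. Without WT2, WT3, WT4, E3 or CE2 it was 0.175, 0.164, 0.157, 0.171 and 0.156. Of the 34 genes that passed in either comparison, 34 had the same sign in both, and 5 higher and 3 lower passed in both, where 0.0044 and 0.0073 would be shared by chance. The shared genes were Selp, Ak3, Uhrf2, Ermp1 and Plpp6 among the higher and Igll1, Vpreb1 and Bfsp2 among the lower. The difference between the effects passed for 0 genes with edgeR (305 genes, or 2.11%, at an unadjusted p under 0.05), 0 with DESeq2 and 0 with limma voom, and for 39 with no filter on low counts. The smallest unadjusted p belonged to genes with low counts: Edar (log2 -3.34), Cacna1c (log2 -3.65), Siglec1 (log2 -3.16), Stab2 (log2 -2.03) and a gene without a symbol, each with group means of at most 2.81 CPM.

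For lists, the difference between the transgene effects passed for 12 of 29, 7 higher and 5 lower on the knockout background, and for 0 with an estimated correlation. With no filter on low counts 13 passed as higher and 1 as lower, and with length and GC trends removed 2 as higher and 5 as lower. The B lineage list passed as lower on the knockout background (22 of 25 members lower, median log2 difference -0.83, camera adjusted p = 1.51e-08, adjusted p = 0.673 with an estimated correlation). In C against WT the list passed as higher (median log2 0.41, camera adjusted p = 0.0043), though not without WT4 (0.184). Set to 0 at the WT mean, the list's mean log2 CPM was 0.20 to 0.64 in C and -0.95 to -0.77 in CE. It was -0.85 to -0.15 in E and -0.56 to 0.71 in WT. The difference therefore rested in part on the level in group C. The B-cell genes Pou2af1 and Blk were at log2 -2.25 and -1.81. Cytosolic ribosomal proteins (median log2 difference 0.22, adjusted p = 1.51e-08, 0.851 with an estimated correlation) included Rplp1 at log2 0.38 and Rps15 at log2 0.36. Interferon-stimulated genes (median log2 difference 0.23, adjusted p = 2.25e-07, 0.711 with an estimated correlation) included Oas2 at log2 0.62 and Oas1a at log2 0.61. The G2/M list passed as lower (median log2 difference -0.10, adjusted p = 0.000459, 0.851 with an estimated correlation). Ccnb1 was at log2 -0.30 and Ccnb2 at log2 -0.26. Nuclear oxidative phosphorylation passed as higher (median log2 difference 0.14, adjusted p = 0.00694, 0.851 with an estimated correlation). Ndufv1 was at log2 0.26 and Ndufs3 at log2 0.23. The stromal and endothelial list passed as lower (median log2 difference -0.80, adjusted p = 0.0135, 0.673 with an estimated correlation). Stab2 was at log2 -2.03 and Vcam1 at log2 -1.04, and no named member of these lists passed alone (adjusted p = 1 for each). Of the 6 lists named here, G2/M was lost without CE3 or WT4 (camera adjusted p = 0.186 and 0.628) and the stromal list without C1 or WT2 (0.128 and 0.072). Nuclear oxidative phosphorylation was lost without C3, CE1, CE3, E2, E3 or WT2 (0.11, 0.0875, 0.0525, 0.0777, 0.153 and 0.916). With no filter on low counts G2/M and the stromal list were lost, and with the Y-linked covariate G2/M and nuclear oxidative phosphorylation. Removing length and GC trends kept 6 of the 12 list calls, and the replicate block 7. With 2 lists higher after that removal, not all of the higher lists named here kept their calls. Leaving out 1 library gave 6 lists without CE1, 7 without WT4 and 8 to 14 without any of the others, and 35 of 100 splits gave as many lists.

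The effect of the caspase loss without the transgene was asked by C against WT. The largest changes were in transcripts that mark sex. Ddx3y, Eif2s3y, Kdm5d and Uty on chromosome Y were at 12.2 to 37.7 CPM in C and at no more than 0.130 CPM in WT. Xist, the transcript of the inactive X chromosome, was at 0.90 ± 0.06 CPM in C and 915.1 ± 292.0 in WT (SD, n = 3 each). The heat shock gene Hspa1a rose 26.8-fold, from 6.60 ± 2.25 to 175.7 ± 111 CPM (SD, n = 3 each, log2 4.74, SE 0.60, adjusted p = 0.00414). Hspa1b rose 21.9-fold, from 10.2 ± 5.48 to 222.3 ± 138 CPM (SD, n = 3 each, log2 4.45, SE 0.62, adjusted p = 0.00747). Reads may have been assigned to either of these near-identical copies. Plcd3, a phospholipase C gene, rose 6.08-fold (log2 2.60, SE 0.35, adjusted p = 0.00636). The calmodulin kinase gene Camk2b rose 3.87-fold (log2 1.95, SE 0.22, adjusted p = 0.00151) and the transcription factor gene Klf4 2.22-fold (adjusted p = 0.046). The eosinophil granule gene Prg3 fell (log2 -2.08, SE 0.42), as did the hematopoietic microRNA gene Mir142 (log2 -1.22) and the macrophage gene Aif1 (log2 -1.01). The noncoding RNA genes Snhg20 (log2 -1.10) and Snord104 (log2 -1.03) and Dpysl2 (log2 -0.96) fell too, these 6 with adjusted p = 0.0395 to 0.0461.

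In total 95 genes passed in C against WT, 52 higher and 43 lower, 9 of them on chromosomes X or Y. In all 95 the groups did not overlap (26.3% of all genes, where chance gives 10%). Of the lists, 10 passed with the preset correlation, 3 higher and 7 lower, and none with an estimated one. The immediate early and heat shock list passed as higher (29 of 29 members higher, median log2 0.56, camera adjusted p = 7.44e-09, adjusted p = 0.615 with an estimated correlation). Over all genes 3 members passed, and 14 adjusted over the list alone. Set to 0 at the WT mean, the list's mean log2 CPM was 0.672 in WT4, -0.332 in WT2 and -0.34 in WT3. It was 0.8951 to 0.9505 in group C, and the list still passed without WT4. Cytosolic ribosomal proteins were lower (73 of 73 members, median log2 -0.38, camera adjusted p = 7.43e-18, adjusted p = 0.658 with an estimated correlation). Over all genes 0 members passed, and 52 adjusted over the list alone. Rps29 was at log2 -0.65 (adjusted p = 0.0595) and Rps3a1 at log2 -0.50 (adjusted p = 0.064). Nuclear oxidative phosphorylation genes were lower (48 of 50 members, median log2 -0.40, camera adjusted p = 2.04e-13, adjusted p = 0.615 with an estimated correlation). None passed over all genes, and 33 adjusted over the list alone. Ndufa2 was at log2 -0.62 and Uqcrb at log2 -0.55 (adjusted p = 0.0513 each). Mitochondrially encoded genes were lower (8 of 8 members, median log2 -0.71, camera adjusted p = 4.89e-05, adjusted p = 0.615 with an estimated correlation). None passed over all genes, and 7 adjusted over the list alone. Set to 0 at the WT mean, this list's mean log2 CPM was -0.582 in WT4, 0.438 in WT2 and 0.144 in WT3. It was -0.7525 to -0.6682 in group C, close to WT4. ND1 was at log2 -0.87 (adjusted p = 0.0501) and ND3 at log2 -1.58 (adjusted p = 0.0525).

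The G2/M phase (median log2 -0.20, camera adjusted p = 0.000272, 0.772 with an estimated correlation) included Birc5 at log2 -0.55 (adjusted p = 0.0549) and Cks1b at log2 -0.52 (adjusted p = 0.0569). Of the list 5 members were lower adjusted over the list alone. Interferon-stimulated genes (median log2 -0.20, camera adjusted p = 0.000674, 0.658 with an estimated correlation) included Isg15 at log2 -0.89 (adjusted p = 0.0567) and Ifitm3 at log2 -0.44 (adjusted p = 0.0665). Of that list 7 members were lower adjusted over the list alone. The B lineage list passed as higher (median log2 0.41, camera adjusted p = 0.0043, 0.658 with an estimated correlation). Of its 25 members 1 passed, the recombinase gene Rag1, which was named after its values were seen. The basophil, eosinophil and mast lineage (median log2 -0.72, adjusted p = 0.0043) and chromosome 9 genes near Casp1 (median log2 -0.31, adjusted p = 0.00566) passed as lower. The sex-specific transcripts passed as higher (adjusted p = 0.00798), and all 3 lists were at adjusted p = 0.615 with an estimated correlation. In the inflammasome and pyroptosis list (33 members) Casp1 alone passed. Leaving out C1, C2, C3, WT2, WT3 or WT4 gave 8, 9, 7, 8, 781 and 2258 genes, and Casp1, Hspa1a, Hspa1b, Plcd3 and Camk2b kept their calls each time. The B lineage and sex-specific lists did not pass without WT4 (camera adjusted p = 0.184 and 0.0689), G2/M without WT2 (0.0673) or the chromosome 9 genes without WT3 (0.0654). With a covariate for Y-linked transcripts Casp1 alone passed, and with the C and WT libraries alone 19 genes. Only group CE held libraries with and without these transcripts, so the covariate rested on CE3 against CE1 and CE2. Over the 94 genes that no longer passed, the median change was 0.79 before and 0.603 after. Their median SE was 0.148 and 0.253, and 93 kept their sign, so the lost calls do not tell sex from genotype. The covariate ended 4 of the 10 list calls, those of the basophil, chromosome 9, interferon-stimulated and sex-specific lists, and having no filter on low counts that of the B lineage. With the covariate Camk2b was at log2 1.87 (SE 0.38) and Hspa1a at log2 2.81 (SE 0.73), with adjusted p = 0.493 each. With trends on transcript length and GC content removed per library, 51 of the 95 genes and 4 of the 10 lists still passed. The ribosomal protein, nuclear oxidative phosphorylation, G2/M, interferon-stimulated, basophil and chromosome 9 lists did not.

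**Figure D4:**
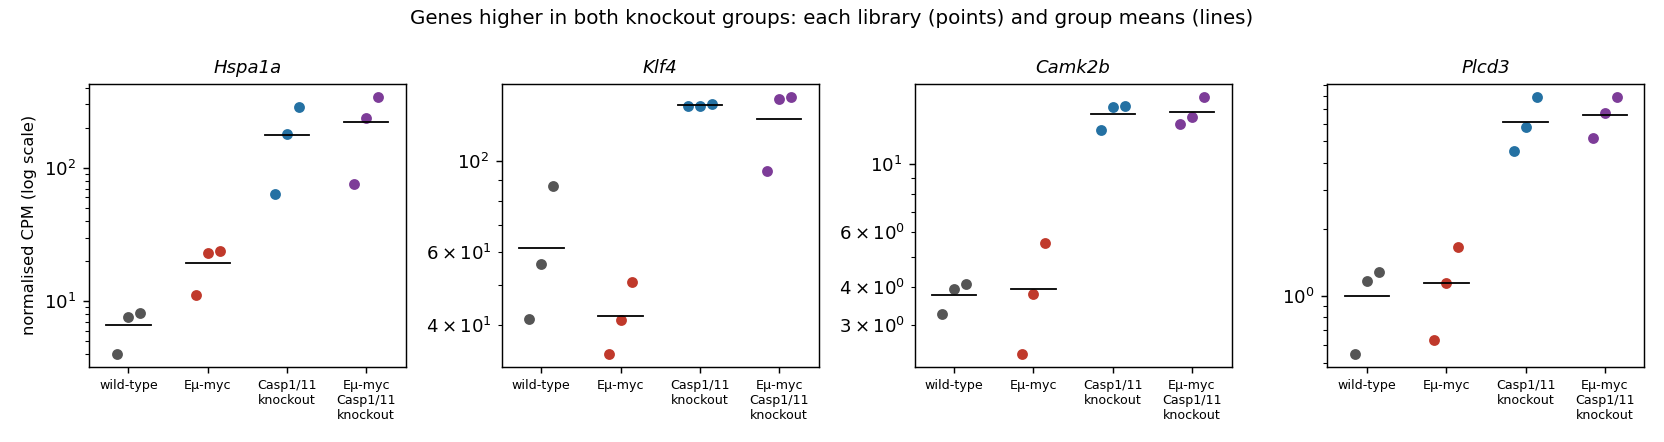
CPM of genes that passed between libraries with and without the caspase knockout label, in each of the 12 libraries by group. The axis is logarithmic, and lines mark group means over 3 libraries. Camk2b was at 3.75 and 3.92 CPM in WT and E and at 14.6 and 14.8 in C and CE.

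The effect of the caspase loss in Eµ-myc mice was asked by CE against E. Immediate early and heat shock genes, which cells induce within minutes of a stimulus or stress, rose. Hspa1a rose 11.4-fold (log2 3.51, SE 0.55, adjusted p = 0.0249) and Hspa1b 9.42-fold (log2 3.24, SE 0.57, adjusted p = 0.0398). Fosb rose 3.02-fold, from 742.5 ± 134 CPM in E to 2238 ± 93.6 in CE (SD, n = 3 each, adjusted p = 0.0398). Egr2 rose 4.07-fold (adjusted p = 0.0439) and Klf4 3.01-fold (adjusted p = 0.0118). Plcd3 rose 5.83-fold (log2 2.54, SE 0.35, adjusted p = 0.0118) and Camk2b 3.76-fold (log2 1.91, SE 0.22, adjusted p = 0.00284). Of the NF-kB and TNF response Ptgs2, an inducible prostaglandin synthase gene, rose 2.93-fold (adjusted p = 0.0306) and Nfkbiz 2.26-fold (adjusted p = 0.0427). Jchain, the joining chain of secreted antibodies, fell 16.2-fold (log2 -4.02, SE 0.82, adjusted p = 0.0398). It was at 76.7 CPM in E1, 85.3 in E2 and 6.48 in E3, and at no more than 4.73 in CE. The interferon-induced GTPase gene Gbp8 fell 4.21-fold and the prostaglandin-degrading enzyme gene Hpgd 2.92-fold. The mitochondrial ribosomal RNA genes mt-Rnr2 and mt-Rnr1 fell 2.69-fold and 2.68-fold, the adhesion molecule gene Vcam1 2.43-fold and the sterol receptor gene Nr1h3 2.35-fold (adjusted p = 0.0398 to 0.0403). Eif2s3y and Ddx3y on chromosome Y passed as higher, with 2 of the 3 CE libraries above 26 CPM and CE3 at 0.131 and 0.0986 CPM.

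In total 229 genes passed in CE against E, 69 higher and 160 lower, 12 of them on chromosomes X or Y. In 227 the groups did not overlap (29.9% of all genes, where chance gives 10%). Of the lists, 14 passed with the preset correlation, 5 higher and 9 lower, and none with an estimated one. The immediate early and heat shock list passed as higher (29 of 29 members higher, median log2 1.03, camera adjusted p = 2.5e-14, adjusted p = 0.475 with an estimated correlation). Over all genes 12 members passed, and 24 adjusted over the list alone. The G2/M list passed as lower (47 of 52 members lower, median log2 -0.31, camera adjusted p = 1.12e-10, adjusted p = 0.501 with an estimated correlation). Over all genes 6 members fell, and 19 adjusted over the list alone. The mitotic genes Ube2c, Ccnb2 and Ccnb1 were at log2 -0.70, -0.55 and -0.54. The nuclear oxidative phosphorylation list passed as lower (43 of 50 members lower, median log2 -0.22, camera adjusted p = 5.22e-07, adjusted p = 0.754 with an estimated correlation). Over all genes 4 members fell, and 12 adjusted over the list alone. Uqcrb, Ndufa4 and Cox7b were at log2 -0.70, -0.60 and -0.57. The list of chromosome 9 genes near Casp1, Casp1 included, passed as lower (16 of 18 members lower, median log2 -0.47, camera adjusted p = 1.67e-06, adjusted p = 0.475 with an estimated correlation). Over all genes Casp1 alone passed, and 7 members adjusted over the list alone. Cytosolic ribosomal proteins passed as lower (median log2 -0.18, camera adjusted p = 1.76e-05, adjusted p = 0.826 with an estimated correlation). The call ended without E1 or CE2 (camera adjusted p = 0.0711 and 0.0702), and the list passed as higher once length and GC trends were removed. Rps3a1 was at log2 -0.48 (adjusted p = 0.068) and Rpl23 at log2 -0.42 (adjusted p = 0.0784).

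Of the remaining lists in CE against E, HSC identity (median log2 0.15, adjusted p = 0.0129), the NF-kB and TNF response (0.29, 0.00514), glycolysis (0.18, 0.0332) and the sex-specific transcripts (adjusted p = 0.0332) passed as higher. Mitochondrially encoded genes (median log2 -0.39, adjusted p = 0.0111), S phase (-0.08, 0.0342), the erythroid lineage (-0.46, 0.0332), the basophil, eosinophil and mast lineage (-0.54, 0.0191) and the monocyte, macrophage and dendritic lineage (-0.27, 0.0342) passed as lower. With an estimated correlation these 9 lists had adjusted p = 0.475 to 0.826. Of these, all but the mitochondrially encoded genes lost their call without at least 1 library. HSC identity was lost without E1 (camera adjusted p = 0.0623), the NF-kB list without CE1 or E2 (0.061 and 0.0636) and the basophil list without CE2 (0.0508). Glycolysis was lost without E2, E3 or CE3 (0.0636, 0.103 and 0.291) and S phase without E1, E2 or CE3 (0.0711, 0.217 and 0.376). The erythroid list was lost without E1, E2, CE2 or CE3 (0.0707, 0.603, 0.124 and 0.139) and the monocyte list without E1, CE1 or CE2 (0.312, 0.0817 and 0.124). The sex-specific list was lost without E2, CE1 or CE2 (0.0625, 0.0817 and 0.0688). Leaving out E1, E2, E3, CE1, CE2 or CE3 gave 4, 8, 23, 2, 2 and 32 genes, and Casp1 and Camk2b kept their calls each time. With a covariate for Y-linked transcripts 2 genes passed, of which Casp1 was among the 229. No E library held these transcripts, so with the covariate the comparison with E rested on CE3. Over the 228 genes that no longer passed, the median change was 0.605 before and 0.688 after. The change was smaller in 82 of them, and the median SE was 0.131 before and 0.186 after. The covariate kept 9 of the 14 list calls and ended those of the NF-kB, basophil, ribosomal protein, monocyte and sex-specific lists. Camk2b was then at log2 1.86 (SE 0.29, adjusted p = 0.0736). With length and GC trends removed, 30 of the 229 genes and 6 of the 14 lists still passed, among the lists immediate early and heat shock genes and G2/M genes. In all, 6 lists were then higher and 3 lower, against 5 higher and 9 lower before. Most of the lower calls therefore ended.

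The 2 effects of the caspase label were compared in the same way. Across 14473 genes, which are not independent replicates, the log2 fold changes of C against WT and CE against E had Pearson's r = 0.526 and Spearman's rho = 0.606. With no filter on low counts r was 0.164, and without CE2 it was 0.264. Of the 284 genes that passed in either comparison, 283 had the same sign in both. Among them 19 higher and 21 lower passed in both, where 0.25 and 0.48 would be shared by chance. Sex nearly coincided with the caspase label in both comparisons, so a difference tied to sex would agree between them too. The agreement therefore does not tell genotype from sex.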

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

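The counts of splits were chosen only after the results were seen; the test of the difference itself was planned. For 12 gene lists the test of the difference between the transgene's effects on the 2 caspase backgrounds passed with the preset correlation, camera being the tool. By adjusted p these were the B lineage (1.51e-08), cytosolic ribosomal proteins (1.51e-08), interferon-stimulated genes (2.25e-07), the G2/M phase (0.000459), nuclear oxidative phosphorylation (0.00694), immediate early and heat shock genes (0.0135), the NF-kB and TNF response (0.0135), stromal and endothelial cells (0.0135), chromosome 9 genes near Casp1 (0.0149), the erythroid lineage (0.0304), mitochondrially encoded genes (0.0426) and interferon-gamma and antigen presentation (0.0458).

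The B lineage list had a median log2 fold change of -0.32 in E against WT and -1.42 in CE against C, and cytosolic ribosomal proteins -0.19 and 0.02. Interferon-stimulated genes had -0.13 and 0.09, and immediate early and heat shock genes -0.40 and -0.06. In C against WT the B lineage list was at a median log2 of 0.41, so its difference rested in part on the level in group C. None of the 12 passed with an estimated correlation (adjusted p = 0.673 to 0.851) or with fry (adjusted p = 0.861 for each). No single gene passed with edgeR (305 at an unadjusted p under 0.05), DESeq2 or limma voom. B lineage, ribosomal protein and interferon-stimulated lists kept their calls without any 1 of the 12 libraries, and the other 9 lists lost theirs without at least 1.

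Other splits of the same libraries gave list counts as large. For the difference, 35 of 100 splits had 12 or more lists, the highest other 16. These splits dealt all 12 libraries to the 4 groups at random, so effects of either genotype could enter the difference. Chance is not excluded for that count. For E against WT 5 of the 10 splits had at least 14 lists (highest other 17), for CE against C 4 had at least 12 (highest other 14), for C against WT 4 had at least 10 (highest other 11), and for CE against E 3 had at least 14 (highest other 15). For genes, 1 of 10 splits, the real one, had as many: 12 against 1 in the highest other for E against WT, 30 against 0, 95 against 0 and 229 against 3 in the order above. With 10 splits a share under 0.05 cannot be reached.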

How the results depend on the processing

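The removal of length and GC trends, the removal of C1 and C3 together, the removal of genes on X and Y and, for named genes, the Y-linked covariate were chosen only after the data were seen; the other alternatives were planned. The order E against WT, CE against C, C against WT, CE against E, difference holds for each series of values here. The reported counts of genes were 12, 30, 95, 229 and 0. With no low-count filter they were 217, 203, 1554, 1172 and 39, and with DESeq2 47, 60, 1255, 1254 and 0. With limma voom they were 17, 109, 1773, 1392 and 0, and with the replicate number as a block 28, 47, 2045, 1475 and 0. With only the compared groups fitted they were 1, 110, 19 and 843. With a Y-linked covariate they were 15, 9, 1, 2 and 0, and with a 2-fold minimum 6, 22, 33, 45 and 0. The RLE factors gave 12, 30, 160, 207 and 0, the stricter filter 12, 26, 219, 303 and 0, and the length and GC offset 17, 36, 133, 31 and 0. The offset moved the share higher from 58.3 to 76.5%, 30 to 44.4%, 54.7 to 39.1% and 30.1 to 51.6%. Leaving out 1 library gave 5 (E3) to 21 (WT4), 2 (CE1) to 13 (C1), 7 (C3) to 2258 (WT4), and 2 (CE1 or CE2) to 32 (CE3) genes, and 0 for the difference. Without C1 and C3, CE against C gave 0 genes with edgeR (282 at an unadjusted p under 0.05), C against WT 4 and the difference 0. Leaving out X and Y gave 12, 30, 86, 217 and 0.

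The reported counts of lists were 14, 12, 10, 14 and 12. With an estimated correlation they were 0, 1, 0, 0 and 0, and with fry 0, 2, 0, 2 and 0. With no filter CE against C gave 6 (4 higher and 2 lower, with 4 of the 12 calls kept) and C against WT 16. The Y-linked covariate kept 13 of 14, 9 of 12, 6 of 10, 9 of 14 and 8 of 12 list calls. The replicate block kept 12 of 14, 12 of 12, 8 of 10, 12 of 14 and 7 of 12. With the Y-linked covariate CE against E gave 9, and with the length and GC offset C against WT gave 5, CE against E 9 and the difference 7. The difference also gave 7 with the replicate block and 3 without C1 and C3. Leaving out 1 library gave 9 to 16 lists for CE against E (9 without E2 or CE2) and 6 to 14 for the difference, while the other 3 comparisons stayed within 1.5 times their counts. The RLE factors kept every list call of all 5 contrasts.

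The agreement of the transgene effects, r = 0.274, was -0.00371 with no filter, 0.435 with the stricter filter, 0.906 over the genes that passed in either comparison and 0.156 to 0.303 without 1 library (lowest without CE2). That of the caspase effects, 0.526, was 0.164 with no filter, 0.684 with the stricter filter, 0.904 over the genes that passed in either and 0.264 to 0.509 without 1 library (lowest without CE2). Among the named genes, the only call to turn its direction was Uty in C against WT, at -0.3534 with the Y-linked covariate, of which it is part. Differences near 0 did: Myc in E against WT (0.03) was -0.002521 with voom, -0.01696 with the block and -0.01855 to 0.07673 without 1 library. Casp1 in E against WT (0.10) was -0.07562 with the block and -0.04683 to 0.2869 without 1 library, and in CE against C (0.05) -0.0399 to 0.1167. For the difference, Casp1 (-0.05) was 0.1322 with the block and -0.2369 to 0.09733 without 1 library, and Casp4 (0.10) -0.1069 to 0.2298. Over all named genes, values without 1 library kept direction and side of the threshold 597 of 900 times, lost a call 274 times, gained 19 and changed sign 10. Casp1 and Selp kept their calls under every alternative run for named genes. Camk2b and, in C against WT, Hspa1a, Hspa1b and Plcd3 did so except with the Y-linked covariate, which for named genes was added after the data were seen and ended 48 calls besides that of Uty. The filter and the 2-fold minimum change which genes are tested or counted, and leaving out libraries lowers their number; otherwise the cause was not tested. The labels do not pair the mice by replicate number. Across genes, deviations from the group means correlated at -0.166 to 0.166 between libraries of the same number in the groups compared. Depth limits genes near the filter, and the simulated 1.5-fold changes were recovered in 10.4 to 44.8% of cases.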

Other observations

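Of the tests here, those of copy gain, of a passenger segment and of the B-lineage pattern were chosen only after the result was seen. So were the gene-by-gene counts after trend removal and Igha. The tests of length and GC content, of sex and of stress were set before their own results, but for patterns already seen. Transcripts of antibody chains varied between mice of one genotype. Igha, the constant region of IgA, was at 495.4 CPM in E1, 30.02 in E2 and 6.13 in E3, at 17.2, 18.4 and 2.69 CPM in CE1, CE2 and CE3, and at no more than 2.70 CPM in any library of WT or C. Jchain was at 76.7 CPM in E1 and 85.3 in E2, and at no more than 21.5 CPM in each of the other 10 libraries. In CE1 and CE2 Jchain was at 3.94 and 1.70 CPM, so it was not raised there along with Igha. Which cells the transcripts came from was not tested.

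The lists that passed in no comparison covered multipotent progenitors (median log2 0.06, 0.05, 0.02 and 0.04 in E against WT, CE against C, C against WT and CE against E), replication-dependent histones (0.11, 0.00, 0.01 and -0.02), inflammasome and pyroptosis (0.01, 0.07, -0.06 and 0.00), p53 targets (-0.07, -0.04, -0.03 and 0.00), the BCL2 family (-0.13, -0.01, 0.06 and 0.00), the neutrophil lineage (-0.03, -0.06, -0.09 and -0.18) and the megakaryocyte and platelet lineage (0.08, -0.05, -0.06 and -0.05). Selp, a platelet gene of the last list, rose in both transgene comparisons while the list had no call. For neutrophils, megakaryocytes, p53 targets, the inflammasome and BCL2 lists the mean and the median, or the test's direction, differed in sign in at least 1 comparison, none of them a call.

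Genes of a segment of chromosome 19 were higher in the Eµ-myc libraries. The segment (28963920 to 30093726) was set from E against WT, and in CE against C, whose libraries took no part in that choice, all 17 tested genes were higher, with a median log2 fold change of 0.66 (bootstrap SE 0.025), where 3 copies over 2 give 0.585 and the flanking 5 Mb on each side (34 genes) gave 0.0132. In E against WT the flank gave 0.142. Vldlr, before the segment's start and within that flank, was at 0.729 and 0.743 in E against WT and CE against C (SE 0.137 each). Cstf2t, beyond the segment's end, was at 0.476 and 0.5 in these comparisons (SE 0.115 each). The limits given here may therefore not bound the rise on either side. None of 13718 other runs of 17 neighbouring genes reached the segment's median in CE against C (highest 0.215). The CE libraries scored 0.656 to 0.778 against 0.0649 to 0.119 in C. Removing length and GC trends left 0.638, which argues against that trend, and a passenger segment with variants of single genes would not move 100% of the genes upward. A candidate explanation is a copy gain of the segment linked to the transgene, which is a hypothesis here, since no DNA was measured.

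The genes that passed between libraries with and without the caspase knockout label could reflect sex, transcript properties or handling as well as genotype. For sex, 82 autosomal genes of C against WT had a median signed log2 change of 0.757, and the difference of CE3, the only CE library without Y-linked transcripts, from E was 0.457, with 79 genes in the same direction, against 0.558 for CE1 and CE2; a single library cannot exclude it. For length and GC, the median signed change of the 229 genes of CE against E fell from 0.607 (median SE 0.131) to 0.411 (0.105) with the trends removed, a ratio of 0.678. Of the 229 genes 30 still passed. Among the 199 that did not, the change was smaller after the removal in 192, the change over its SE in 173 and the unadjusted p larger in 176. Their median change was 0.589 before and 0.376 after, and their median SE 0.128 and 0.101. These 199 were picked by the loss of their call, so such shifts are in part built in and do not judge the explanation. For stress at isolation, the immediate early score and the score of the other 252 autosomal genes, as deviations from group means over 12 libraries, had r = 0.475 and rho = 0.168 (exact permutation p = 0.616 and 0.736, adjusted for neither, 1296 arrangements), and r = 0.17 without WT3 and WT4, the farthest on the x axis. Casp1, the targeted gene, is apart from this, at 5.72 CPM in CE3 against 37.8 to 45.1 in E. For the other genes these explanations and the genotype were not told apart.

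B-lineage genes lay lower in CE than in C (24 of 25 members). In E against WT 16 of 25 were lower, and the list's score in WT4 (-0.555) was below E1 and E2 (-0.154 and -0.223). A like fall of every other cell type is argued against, since in CE against C the monocyte list lay at a median log2 of -0.0284, the megakaryocyte list at -0.0466 and the neutrophil list at -0.059, far above the B lineage at -1.42, while the erythroid list lay at -1.03, the basophil, eosinophil and mast list at -0.382 and the T and NK list at -0.351, so fewer cells of these types stay open. The cells were sorted as stem cells, by a gate not given in the sources used here, and such a sort would remove most B-lineage cells. Fewer B-lineage cells left in it would lower the genes by about the same amount: the 13 genes that fell in CE against C had an SD of 0.387 there, where they were chosen, and of 0.859 in E against WT, with all 13 lower and a median SE of 0.357, which leaves it open. Fewer lymphoid-primed progenitors also stay open, with 7 priming genes at a median log2 of 0.00572 (bootstrap SE 0.135) in CE against C, members going both ways. Whether the transgene acted within the stem cells was not tested.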
